A study of Mus musculus with 4 samples.

How the data were processed

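RNA from mouse cells described as primary lung fibroblasts was sequenced as 4 libraries, 2 with the genotype label Calu-WT (called WT here) and 2 with the label Calu-KO. Groups were taken from the genotype labels, and replicate numbers from the sample descriptions. Per the labels' protocols, RNA was extracted with TRIzol, libraries were sequenced on an Illumina NovaSeq 6000, and paired-end reads were aligned with HISAT2 2.0.5. Per the submitters' processing notes, the genome build was mm10. The read counter, the gene annotation, the use of strand in counting and the program that made the expression values are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart.

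The authors deposited 1 table of FPKM values (fragments normalised to gene length and library size) for 54532 genes, with 1 column per library and the gene length, biotype and coordinates of each gene. Multiplying each FPKM by the gene length gave whole multiples of 1 step per library for 100% of values, within a tolerance of 0.001 reads, so reads per gene were recovered. The recovered totals were 15635448 and 16033535 reads in WT replicates 1 and 2, and 16510048 and 16038560 in Calu-KO replicates 1 and 2. The library sizes that these steps imply equalled median-of-ratios size factors times the geometric mean of the totals, so the deposited FPKM columns were already scaled between libraries. At this depth 1 read in a gene of 1 kb was worth 0.0592 to 0.0684 FPKM, and 3 reads, used as the floor for a gene with no reads, 0.177 to 0.205 FPKM. Counting intervals and floors cover counting error only. Of the table's rows, 54495 were found in the GENCODE M21 annotation by identifier, and 53585 of them had the same start and end. Coordinates are those of the deposited table, in mm10.

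Replicates were compared before they were averaged. Over genes with at least 100 reads in a pair, the mean chi-square per gene was 3.90 for the 2 WT libraries and 49.2 for the 2 Calu-KO libraries, and the median 1.22 and 9.76. Both pairs differed by more than counting error, so neither was treated as a single library, but the WT pair is close enough that technical repeats are not excluded. Expression was analysed as log2(FPKM + 1), a scale that understates the change of low genes. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 11885 in all. Calu-KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity-dependent prior), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values throughout are from limma. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. Fold differences are ratios of mean FPKM. The fold of a gene with 1 to 3 reads in a group is given with its exact 95% binomial counting interval, and a gene with no reads is set at 3 reads over both libraries of the group.

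Gene lists (36, for pathways, complexes and markers of other cell types) were fixed before the data were examined. Those with 3 or more tested genes, 32 lists, were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were the alternatives. With an estimated correlation, camera tests on the residual degrees of freedom, 2 here, whatever the correlation. The lowest adjusted p of the 32 lists was then 0.527, so a call lost there does not show that correlation undid it. The rule for named genes was fixed at the same time. It took Calu, Vim and the other CREC family genes, and the 10 protein-coding genes per direction with the greatest change among those past the threshold and with separated groups. It also took up to 4 members past the threshold from each list, and Acta2, Col1a1, Col3a1, Fn1, Hspa5, Ddit3 and Sqstm1. Some genes that the rule took are not reported here by name. A scan for runs of neighbouring genes with a shared change was added after the data were seen. It summed log2 changes less an offset of 0.4, also chosen after the data were seen, and compared the highest sum with those of 1000 permutations of gene positions. The same sum was also run on Calu-KO minus WT of 1 replicate number alone, and the stretch found was measured in the libraries of the other number. This, like the share of scanned genes that were higher in each Calu-KO library, restates how the stretch was found, and both were set aside as tests of a copy gain. The test kept uses genes of the stretch with a mean under 1 FPKM and at least 20 reads over the 4 libraries, as log2 ratios of mean scaled reads with 0.5 added, against such genes elsewhere.

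The steps were tested on simulated data. In 5 simulations of the Calu-KO against WT comparison, with 200 of 11885 genes changed, 44.5% of log2 changes of 1 and 95.4% of log2 changes of 2 were found, and 2.70% of calls were unchanged genes. A shifted list was found, with 0 other lists called. Genes were simulated as independent, so this does not show how often lists of correlated genes would be called. With 100 neighbouring genes raised by 0.8 on the log2 scale among 11885 permuted changes, the scan returned a segment that held all 100.

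Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a minimum of 5 FPKM, median-of-ratios scaling, columns rescaled to a common sum, quantile normalization, eBayes without a trend and with a robust prior, the replicate number as a block, each library left out in turn, a minimum absolute log2 change of 1, a threshold of 0.01 and protein-coding genes only. Alternatives added after the data were seen were rescaling by the total of recovered reads, limma voom on the recovered reads, removal of each library's trend on GC content and gene length, and the fit without the genes of 1 chromosome 12 segment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.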

Results

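Gene expression was measured by RNA sequencing in 2 WT and 2 Calu-KO libraries of mouse cells labelled as primary lung fibroblasts. Of 6 transcription factor genes of lung mesenchyme, picked after the data were seen, 0 reached 1 FPKM in any library, so this origin is taken from the labels alone. Calu encodes calumenin, a calcium-binding protein of the endoplasmic reticulum (ER) and secretory pathway and a member of the CREC family. The genotype label calls the targeted libraries a knockout, whereas their titles carry the letters KD, and how the gene was targeted was not given in the sources used here. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Recovered reads were even, at 15635448 to 16510048 per library. Fewer genes had a read in Calu-KO (19772 and 18739 in replicates 1 and 2) than in WT (20477 and 20429). The 50 genes with the most reads took 13.9% of reads in Calu-KO replicate 2, and 11.1% to 11.7% in the other libraries. Across genes, which are not independent replicates, log2 expression of the 2 WT libraries correlated at 0.989 and of the 2 Calu-KO libraries at 0.966. Calu-KO replicate 2 stood farther from the WT libraries (0.938 and 0.939) than Calu-KO replicate 1 (0.964 with each), and mitochondrial genes took 4.0% of its reads against 2.43% to 2.53% in the other 3 libraries.

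The comparison of Calu-KO with WT asked how the transcriptome of these cells differs when calumenin is lost, in a study concerned with protein folding, vimentin and fibrosis. Calu (ENSMUSG00000029767, chromosome 6, 29348069 to 29377110, mm10, protein coding) stood at 178 and 177 FPKM in the WT libraries and at 14.9 and 10.9 FPKM in the Calu-KO libraries. Its mean fell 13.7-fold, from 178 ± 0.444 to 12.9 ± 2.84 FPKM (SD, n = 2 each), a log2 change of -3.70 ± 0.17 (SE; adjusted p = 0.00493, limma). The Calu-KO libraries still held 1178 and 744 Calu reads, and gene-level values do not show from which exons. Vim, which encodes the intermediate filament vimentin, stood at 592 ± 5.75 FPKM in WT and 590 ± 84.4 FPKM in Calu-KO, a log2 change of -0.01 ± 0.15 (adjusted p = 0.971). None of the other 4 CREC genes passed the test over all genes (of the 5, Rcn3 rose and Calu fell when adjusted over the list alone; list adjusted p = 0.679). Log2 changes were 0.14 ± 0.11 for Rcn1, -0.04 ± 0.12 for Rcn2, -0.08 ± 0.10 for Sdf4 and 0.68 ± 0.19 for Rcn3 (adjusted p = 0.130).

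**Figure D1:**
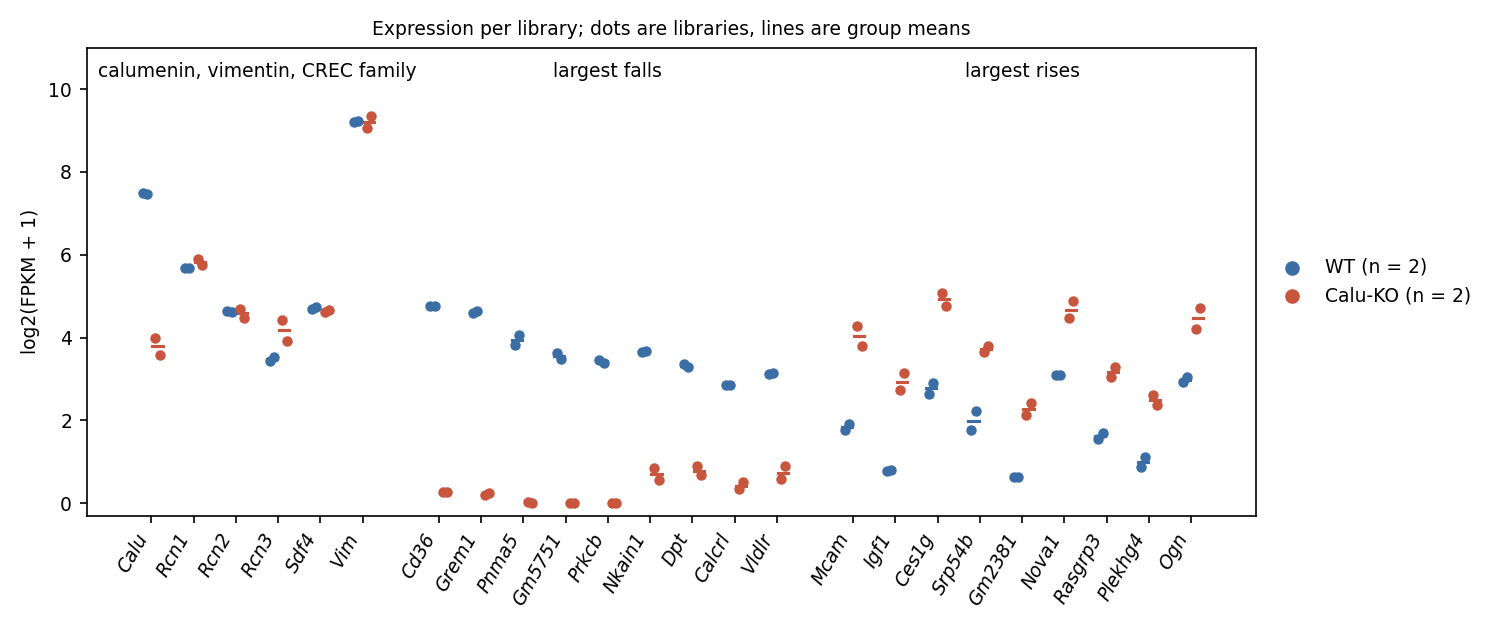
Expression of single genes in each library, as log2(FPKM + 1) on the vertical axis, for Calu, Vim and the CREC family and for protein-coding genes with the greatest falls and rises. Blue dots are the 2 WT libraries, red dots the 2 Calu-KO libraries and short lines group means; Calu is lower in both Calu-KO libraries (14.9 and 10.9 FPKM) than in both WT libraries (178 and 177 FPKM), while the Vim dots of the groups overlap.

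Of 11885 genes tested, 112 were higher and 217 lower in Calu-KO than in WT, 61 and 154 of them by at least 1 on the log2 scale. Among protein-coding genes, on the log2(FPKM + 1) scale, the greatest falls were those of Cd36, a fatty acid scavenger receptor, from 26.1 ± 0.235 to 0.212 ± 0.00317 FPKM (123-fold, adjusted p = 0.00154), and of Grem1, a secreted antagonist of bone morphogenetic proteins, from 23.5 ± 0.556 to 0.162 ± 0.0275 FPKM (145-fold, adjusted p = 0.00154). Prkcb, which encodes protein kinase C beta, had 1259 and 1196 reads in WT and 1 read in each Calu-KO library, 0.000857 of its WT level, with a counting interval for the fold of 324 to 9691. Pnma5 had 671 and 812 reads in WT and 1 and 0 in Calu-KO, 0.000658 of its WT level, with an interval of 254 to 56012. Gm5751, at 10.7 ± 0.786 FPKM in WT, had no reads in Calu-KO and was at least 50.01-fold lower. Nkain1 fell 18.5-fold, Calcrl, a receptor for calcitonin gene-related peptide and adrenomedullin, 18.1-fold, Dpt, the matrix protein dermatopontin, 12.4-fold, and the lipoprotein receptor gene Vldlr 11.5-fold.

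The greatest rises of protein-coding genes on this scale were smaller. Mcam, a cell adhesion molecule used as a pericyte marker, rose 6.04-fold, from 2.60 ± 0.242 to 15.7 ± 3.85 FPKM (log2 change 2.20 ± 0.19, adjusted p = 0.0251). Igf1, insulin-like growth factor 1, rose 9.24-fold, from 0.728 ± 0.0358 to 6.73 ± 1.59 FPKM (log2 change 2.15 ± 0.19, adjusted p = 0.0253). Ces1g, a carboxylesterase, rose 4.99-fold, the Ras activator gene Rasgrp3 3.84-fold, Plekhg4 4.65-fold, Gm2381 7.04-fold and Ogn, the small proteoglycan osteoglycin, 3.10-fold. Nova1, which encodes a splicing factor, rose 3.31-fold and Srp54b, a subunit of the signal recognition particle, 4.02-fold. Srp54b and Ces1g have close paralogs, so the share of reads given to each is uncertain.

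In 1 stretch of chromosome 12 (21240825 to 59012017, from Itgb1bp1 to Sec23a, mm10) neighbouring genes were higher in Calu-KO. It was found by a scan of the same log2 changes, chosen after the data were seen, so the values of its genes are not an independent test. It held 90 tested genes, 0.757% of all, and 34 of the 112 genes called higher, 30.4%, among them Nova1, Srp54b and the ribosomal protein gene Rps7. The median log2 change of the 90 genes was 0.77, with 0.76 in each Calu-KO library. Of the 90, 82 lay above the WT mean in each. For the 330 tested genes on the rest of the chromosome the median was 0.02, and the median difference between the WT libraries in the stretch was 0.04. Without these genes 66 genes were higher and 187 lower.

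**Figure D2:**
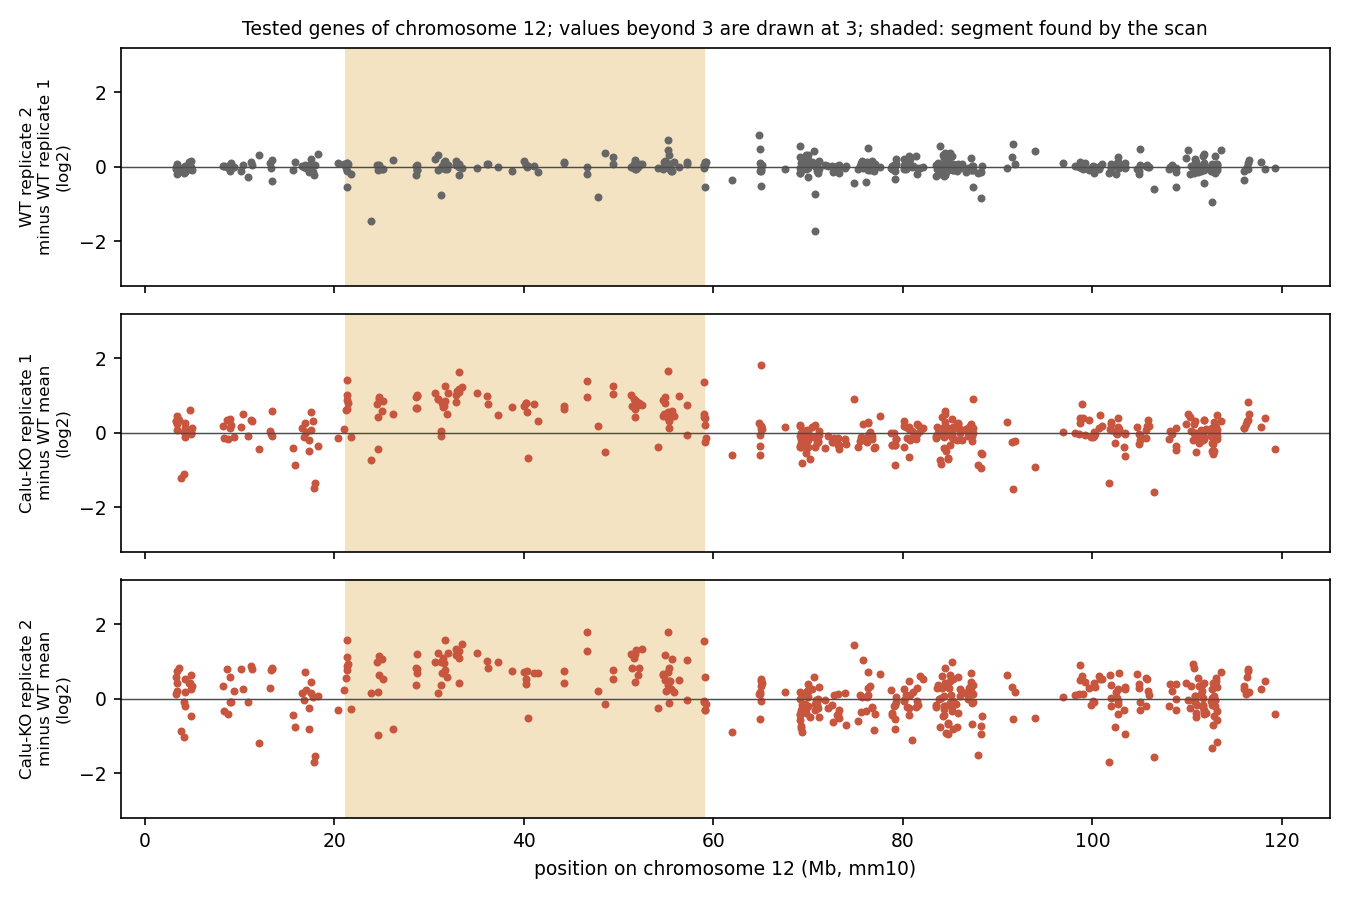
Log2 differences of tested genes along chromosome 12, with position in Mb (mm10) on the horizontal axis and the log2 difference of FPKM + 1 on the vertical axes; each dot is a gene. The panels show WT replicate 2 minus replicate 1 and each Calu-KO library minus the WT mean; in the shaded stretch from 21.2 to 59.0 Mb, chosen on these changes, 82 of 90 genes lie above 0 in each Calu-KO library, whereas the median difference between the WT libraries there is 0.04.

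The number of calls rested on which libraries entered: 10 genes were higher and 38 lower without WT replicate 1, 8 and 34 without WT replicate 2, 2926 and 2805 without Calu-KO replicate 1, and 922 and 1130 without Calu-KO replicate 2, where the lone library is assumed to vary like the pair. Of 50 genes past the threshold that the naming rule took, 15 passed without either WT library in turn (Calu, Cd36, Grem1, Pnma5, Gm5751, Prkcb, Nkain1, Dpt, Calcrl, Vldlr, Lcn2, Hist1h1c, Mcam, Igf1 and Ces1g). With no filter on low values no gene passed (limma; 3886 genes at an unadjusted p under 0.05). Rcn3, Ddit3, Fn1 and Hspa5 passed with either Calu-KO library left out, and Col1a1 without Calu-KO replicate 1. In those fits the spread within a group came from the WT libraries alone, so passing there adds no support. Over 18 alternatives the log2 change ran from 0.43 to 0.98 for Rcn3 and from -1.70 to -0.92 for Ddit3. It ran from -0.77 to -0.36 for Fn1, -0.70 to -0.45 for Hspa5 and 0.22 to 0.58 for Col1a1. Rescaling by total reads gave 45 higher and 152 lower genes, 22.8% higher against 34.0%.

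Of 40 tested genes of autophagy and the lysosome, 4 fell and none rose (14 fell when adjusted over the list alone), 35 had a negative log2 change and the median was -0.31. The list passed the camera test (adjusted p = 8.1e-07), but not with its correlation estimated (adjusted p = 0.527 with an estimated correlation). The estimate, 0.00697, was under the preset 0.01, so for this list a higher correlation is not the reason. That test has 2 residual degrees of freedom. The 4 were Ctsk, the cysteine protease cathepsin K (48.4 ± 0.413 to 15.5 ± 2.97 FPKM, 3.11-fold), Gla and Hexa, which encode lysosomal glycosidases (1.97-fold and 1.82-fold), and Sqstm1, the autophagy receptor p62 (176 ± 3.83 to 107 ± 2.42 FPKM, 1.65-fold, adjusted p = 0.0451). The call on Sqstm1 held in 8 of 18 alternatives. Among 29 genes of ER chaperones and ER-associated degradation, 2 fell (2 rose and 9 fell when adjusted over the list alone), and the list was lower as a set (median -0.17, adjusted p = 0.00821; adjusted p = 0.527 with an estimated correlation). These were Creld2, at 106 ± 5.35 and 50.5 ± 4.81 FPKM, and Sdf2l1, at 71.4 ± 5.41 and 31.6 ± 0.0275 FPKM, both induced by the unfolded protein response. Hspa5, the main ER chaperone BiP, stood at 825 ± 8.08 FPKM in WT and 555 ± 68.4 in Calu-KO (log2 change -0.58 ± 0.14, adjusted p = 0.105).

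Of 31 genes of the integrated stress response, 2 fell (5 when adjusted over the list alone), namely Ppp1r15a, a phosphatase subunit that reverses the response (3.004-fold), and Vldlr, and the list did not pass (adjusted p = 0.108). It did pass, as lower, without WT replicate 1 (0.0406), WT replicate 2 (0.0326) or Calu-KO replicate 2 (0.0198), and with fry (0.0181). Ddit3, the stress transcription factor CHOP, had a log2 change of -1.31 ± 0.27 (65.4 ± 1.73 against 26.8 ± 10.4 FPKM, adjusted p = 0.0796). No member passed among 25 cytosolic heat-shock chaperones (list adjusted p = 0.679), 31 proteasome subunits (0.199, and 0.0481 without Calu-KO replicate 1) or 19 genes of calcium handling (0.757), and in each of these lists 0 members passed when adjusted over the list alone.

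Matrix genes moved both ways. Of 16 fibrillar and basement-membrane collagens 1 fell (1 rose and 2 fell when adjusted over the list alone). This was Col3a1, the fibrillar collagen III chain, at 39.1 ± 0.334 FPKM in WT and 12.03 ± 0.178 in Calu-KO (3.25-fold, log2 change -1.62 ± 0.10, adjusted p = 0.0115). Col1a1, a chain of collagen I, did not pass, at 126 ± 6.37 against 167 ± 29.6 FPKM (log2 change 0.40 ± 0.16, adjusted p = 0.208), nor did fibronectin, Fn1, at 154 ± 0.694 against 105 ± 21.02 FPKM (-0.56 ± 0.17, adjusted p = 0.137). Of 20 other matrix genes 3 rose and 5 fell (3 and 7 when adjusted over the list alone). Ogn and the leucine-rich proteoglycan gene Prelp rose (Prelp 2.12-fold), while the proteoglycan gene Vcan fell 4.85-fold and Fbln5, needed for elastic fibres, 6.29-fold. Neither the collagens (adjusted p = 0.679) nor the other matrix genes (adjusted p = 0.127, and 0.0195 without Calu-KO replicate 2) passed as a list. Of 11 matrix-degrading enzymes and inhibitors Adamts5, an aggrecanase, rose 3.17-fold and the metalloproteinase gene Mmp19 fell 6.08-fold (2 rose and 2 fell when adjusted over the list alone; list adjusted p = 0.679). Among 19 genes of collagen processing none passed (1 rose and 1 fell when adjusted over the list alone; list adjusted p = 0.132).

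Of 22 genes of the TGF-beta pathway, a main driver of fibrosis, 2 rose and 2 fell (5 and 4 when adjusted over the list alone; list adjusted p = 0.780). The ligand gene Tgfb1 fell 2.13-fold, whereas the receptor gene Tgfbr2 rose 1.91-fold and Tgfbi, a target of the pathway, 1.81-fold. Of 18 contractile and myofibroblast genes Pdlim7 fell 2.44-fold and Des, the intermediate filament protein desmin, 2.02-fold (2 fell when adjusted over the list alone). The list did not pass (adjusted p = 0.802), and its median was 0.08 where its mean and test were negative. Acta2, the smooth-muscle actin that marks myofibroblasts, was below the filter, with 3 and 2 reads in WT and 0 in Calu-KO. Of 9 genes of intermediate filaments and their linkers Des and Krt8, a keratin, fell (1 rose and 3 fell when adjusted over the list alone; list adjusted p = 0.261), Krt8 from 2.51 ± 0.332 to 0.0652 ± 0.00671 FPKM.

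**Figure D3:**
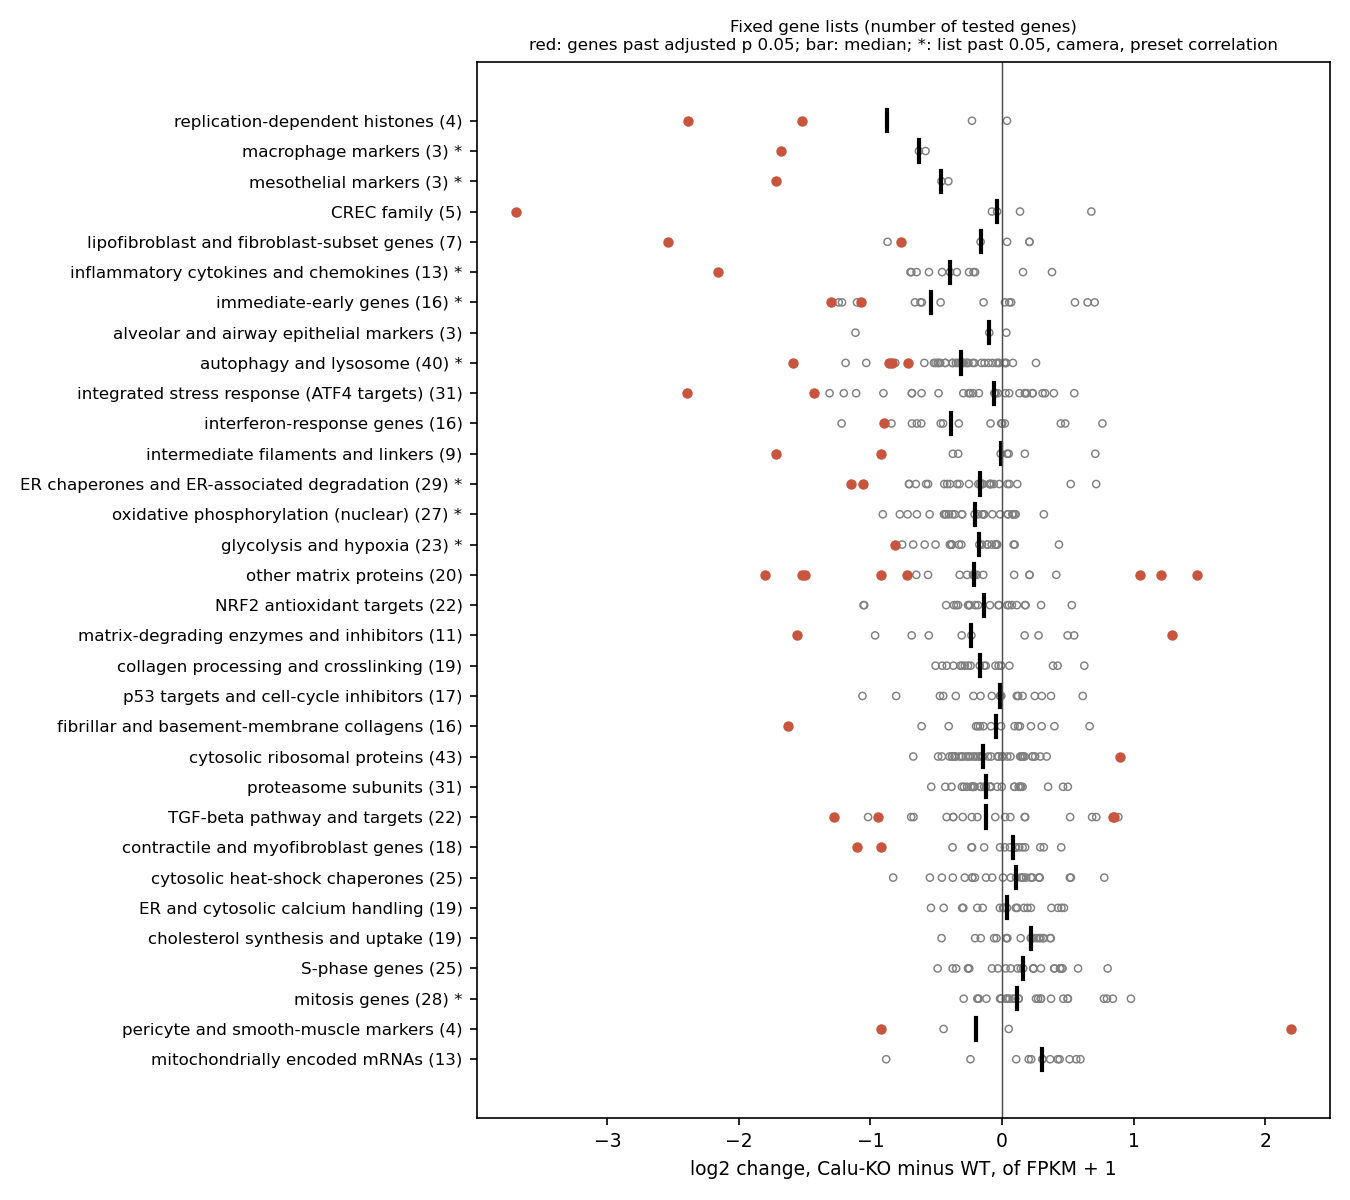
Log2 change of FPKM + 1 (Calu-KO minus WT, horizontal axis) of every tested member of the 32 fixed gene lists with at least 3 tested genes, ordered by the mean of the list. Each circle is a gene, filled red where it passed an adjusted p of 0.05; black bars are medians and asterisks mark the 9 lists past camera with the preset correlation, such as autophagy and lysosome with a median of -0.31.

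Of 13 cytokine, chemokine and related genes, Lcn2, the siderophore-binding lipocalin 2, fell 6.49-fold and no other passed (2 fell when adjusted over the list alone; list adjusted p = 0.00821; adjusted p = 0.527 with an estimated correlation). Of 16 immediate-early genes Egr1, a transcription factor, fell 3.75-fold and Dusp5, a phosphatase of ERK, 2.67-fold (3 rose and 9 fell when adjusted over the list alone; list adjusted p = 0.0295; adjusted p = 0.527 with an estimated correlation). Of 16 interferon-response genes Tap1, the peptide transporter, fell 2.04-fold (1 rose and 6 fell when adjusted over the list alone; list adjusted p = 0.105, and 0.0404 without WT replicate 1). Of 23 genes of glycolysis and hypoxia Hk1, a hexokinase, fell 1.84-fold (3 when adjusted over the list alone; list adjusted p = 0.00821; adjusted p = 0.527 with an estimated correlation). No single gene passed among 27 nuclear genes of oxidative phosphorylation, lower as a list (adjusted p = 0.0295; adjusted p = 0.638 with an estimated correlation), or 28 mitosis genes, higher as a list (median 0.11, adjusted p = 0.0280; adjusted p = 0.527 with an estimated correlation), and none did when adjusted over either list alone. Log2 changes were lower in genes of higher GC content (Spearman's rho -0.315, across genes). With that trend and the trend on gene length removed, 4 of the 9 lists passed, and those of glycolysis (adjusted p = 0.0658), oxidative phosphorylation (0.183), mitosis (0.0658), immediate-early genes (0.109) and mesothelial markers (0.0658) did not. Their mean log2 changes relative to all tested genes were smaller but kept their sign. They went from -0.23 to -0.18 for glycolysis, -0.23 to -0.14 for oxidative phosphorylation and 0.23 to 0.16 for mitosis. For immediate-early genes the values were -0.38 and -0.25, and for mesothelial markers -0.84 and -0.64. Some of these calls were also lost with 1 library left out. For oxidative phosphorylation the mean log2 change relative to all tested genes was then -0.22 without WT replicate 2 and -0.076 without Calu-KO replicate 2, against -0.23 with all libraries. For mitosis it stayed near the 0.23 of all libraries, at 0.21 without WT replicate 1 and 0.26 without Calu-KO replicate 1. For immediate-early genes it was -0.30 without Calu-KO replicate 2, against -0.38.

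Markers of other cell types were mostly under the filter. None of the lymphocyte, neutrophil and erythroid genes were tested, and neither of the 2 tested endothelial genes passed. Of 3 tested macrophage markers Lyz2, lysozyme, fell 4.67-fold, from 6.91 ± 0.451 to 1.48 ± 0.325 FPKM (3 fell when adjusted over the list alone), and the list was lower (adjusted p = 0.00975; adjusted p = 0.527 with an estimated correlation). Of 3 mesothelial markers Krt8 fell (3 when adjusted over the list alone), and the list was lower (adjusted p = 0.0235, and 0.527 with an estimated correlation). Its mean log2 change relative to all tested genes was -0.84, but -0.22 with no filter on low values (camera adjusted p = 0.291). Rescaling by total reads kept the value (-0.84) but not the call (camera adjusted p = 0.0540). Of 4 pericyte markers Mcam rose and Des fell, also when adjusted over the list alone. The list did not pass (adjusted p = 0.780), with a positive mean of 0.22 and a negative median and test. Among 3 epithelial markers none passed (1 fell when adjusted over the list alone; list adjusted p = 0.339). Of 7 lipofibroblast and fibroblast-subset genes Dpt fell, as did Plin2, which coats lipid droplets, 1.71-fold (2 when adjusted over the list alone; list adjusted p = 0.148).

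Of 4 tested replication-dependent histone genes Hist1h1c fell 5.83-fold and Hist1h2bc 4.06-fold (2 when adjusted over the list alone; list adjusted p = 0.0519, 0.0205 without WT replicate 1 and 0.00746 without WT replicate 2). Reads of such near-identical genes may be split between copies. Of 43 cytosolic ribosomal protein genes Rps7, in the chromosome 12 stretch, rose 1.86-fold, from 328 ± 4.29 to 612 ± 44.1 FPKM (1 rose when adjusted over the list alone; list adjusted p = 0.369, and 0.0213 without Calu-KO replicate 1). No gene passed among 25 S-phase genes (list adjusted p = 0.10, and 0.0298 without Calu-KO replicate 2), 19 genes of cholesterol synthesis (0.108), 22 NRF2 antioxidant targets (0.261), 13 mitochondrially encoded mRNAs (0.226, and 0.00530 without Calu-KO replicate 1) or 17 p53 targets and cell-cycle inhibitors (0.757), where 1 rose when adjusted over the list alone and 0 did in the other 4.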

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

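The rescaling by total reads, voom, the removal of GC and length trends and the fit without the chromosome 12 stretch were tests chosen after the data were seen; the others were planned. Calu was lower in each of 18 alternatives (-3.91 to -3.49) and passed in 17, missing without a filter (log2 change -3.70, adjusted p = 0.0797), where 0 genes were higher and 0 lower among 24462 genes tested. Genes higher and lower were 71 and 132 with a pseudocount of 0.01, 0 and 10 at a threshold of 0.01, 273 and 448 with protein-coding genes alone (91 and 198 of the main calls), 361 and 469 with voom and 257 and 329 with GC and length trends removed. There were 61 higher at an absolute log2 change of 1, 66 without the chromosome 12 stretch, 45 with total reads and 130 lower with at least 5 FPKM; where the construction (fewer genes, a stricter threshold) does not show it, the cause was not tested. Leaving out 1 library gave 8 to 2926 higher and 34 to 2805 lower genes, the fewest without a WT library and the most without Calu-KO replicate 1. The replicate block gave 181 higher and 312 lower genes, but same-numbered libraries share only a number (correlation of their deviations 0.0153). Median-of-ratios scaling moved nothing, since the columns already had it. Of 9 lists past the threshold, 0 passed with an estimated correlation, a test on 2 residual degrees of freedom, and 4 with the GC and length trends removed. With fry 11 passed, 5 of them shared. For cytokines (0.235), oxidative phosphorylation (0.238), mesothelial markers (0.437) and mitosis (0.0610) the estimated correlation was above the preset 0.01. It was lower for the rest of the 9 lists. Where it was above, a higher correlation and the few degrees of freedom cannot be told apart as the reason for the lost call.

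Results whose direction turned had not passed the threshold with all libraries. With 1 library left out, the log2 change of Vim ran from -0.16 to 0.14 and of Rcn2 from -0.15 to 0.074. For lists, whose values are mean log2 changes relative to all tested genes and whose direction is that of the test, the ranges were 0.14 to 0.34 for pericyte markers, -0.098 to 0.011 for contractile genes, -0.15 to -0.00029 for collagens, -0.70 to -0.46 for the CREC family, -0.079 to 0.18 for calcium handling, -0.19 to 0.027 for p53 targets, -0.047 to 0.53 for mitochondrial mRNAs and -0.19 to 0.045 for ribosomal proteins. Removing GC and length trends turned heat-shock chaperones (0.023), calcium handling (-0.0047), contractile genes (-0.012) and ribosomal proteins (0.047), and fry turned pericyte markers (0.24). The causes were not tested. Over the other combinations of a named gene and an alternative, 846 kept direction and side of the threshold, 163 lost the threshold and 15 gained it; for lists these were 572, 27 and 22.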

Other observations

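The tests of MAPK output genes, scaling, cell origin, transcription factor depth, the Cdkn2a locus and the splits of the libraries were chosen only after the result was seen; those of GC content, copy gain, read number and regional deletion were set down before their results, that of copy gain after the stretch itself and other tests of it had been seen. Of 9 tested genes of a 10-gene list of MAPK pathway output, 4 fell and none rose (5 fell when adjusted over the list alone): Dusp6 (20.9 ± 0.266 to 8.84 ± 0.166 FPKM), Dusp4 (15.1 ± 0.0295 to 6.34 ± 0.931), Etv5 (16.5 ± 0.386 to 6.30 ± 1.04) and Spry4 (6.70 ± 0.199 to 3.50 ± 0.246; SD, n = 2 each). The list had an unadjusted camera p of 0.000321, and of 0.0798 with an estimated correlation. It was picked because such genes had been seen among the calls, so this is not independent evidence. None of the 9 passed over all genes without WT replicate 1 or without WT replicate 2 (limma; 3 and 4 fell when adjusted over the list alone), while 1 rose and 6 fell without Calu-KO replicate 1, and Ccnd1 (112 ± 1.05 and 110 ± 13.6 FPKM) and Spry2 (8.12 ± 0.268 and 8.38 ± 3.23 FPKM) did not pass with all libraries.

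A stretch of chromosome 17 from Cenpq to Hsp90ab1 (40923051 to 45573271, mm10) held 16 tested genes with a median log2 change of 0.74, and its scan p of 0.001 was the smallest that 1000 permutations give. Its score of 4.97 lay only just above the highest permuted score, 4.67, against 28.2 for the chromosome 12 stretch. Permuted positions ignore trends shared by neighbours, and a trend on GC content was not checked for this stretch. The 3 splits of the 4 libraries into 2 and 2 are too few for a share under 0.05; 1 of the 3, the real one, called 329 genes, and the highest other called 0 (limma; 98 and 96 genes at an unadjusted p under 0.05 in the other 2).

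The raised stretch of chromosome 12 scored 28.2 in the scan, against 4.67 for the highest of 1000 permutations. A trend on GC content, gene length or expression does not account for it, since the median log2 change stayed at 0.65 (bootstrap interval 0.58 to 0.75) with those trends removed. Scaling between libraries shifts all genes alike, so it cannot raise 1 stretch alone. The median for the rest of the chromosome was 0.020, but the columns were already scaled, so a value near this was likely in advance. A copy gain in the cells of both Calu-KO libraries is a candidate explanation: it needs genes there that the scan did not use to be higher too, and in 27 genes under the filter, with at least 20 reads over the 4 libraries, the median log2 change was 1.03 above that of 3540 such genes elsewhere (bootstrap interval 0.40 to 1.62), though reads of raised neighbours may add to them, as the use of strand in counting is not given. Both bootstrap intervals resampled genes, with neighbours treated as independent, so they do not measure the spread between libraries. No DNA was analysed here, and a selected or drifted cell population and the genotype itself stay open, since all Calu-KO libraries carry the pattern.

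The libraries lacked several transcripts of lung mesenchyme. Of 6 transcription factor genes of lung mesenchyme (Tbx2, Tbx4, Tbx5, Foxf1, Tcf21 and Meox2), 0 reached 1 FPKM in any library, the highest value being 0.142 FPKM, and Thy1, Twist1, Cdh11 and Lox, common fibroblast genes, reached at most 0.137 FPKM, while Pdgfra and Col1a2 stood at 11.5 ± 0.182 and 232 ± 3.22 FPKM in WT. Depth does not account for this, as 6 of 7 HOX genes of paralog groups 9 and 10 reached 1 FPKM in every library (Hoxa10 at 22.5 ± 1.17 and Hoxc10 at 41.1 ± 1.12 FPKM in WT). The cells may therefore not be freshly isolated lung mesenchyme, against the labels, and an established line is a candidate explanation, as Cdkn2a and Cdkn2b had 0 reads over the 4 libraries where their neighbours Mtap and Klhl9 had 355 and 6658; a silent locus would give the same value. Xist had 0 and 1 reads in WT and 6 and 8 in Calu-KO (counting interval for the fold 2.23 to 619), a trace whose source was not tested, and Ddx3y, Kdm5d, Eif2s3y and Uty had 0.

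Some genes were silent in Calu-KO alone. With at least 2 FPKM in both WT libraries and at most 0.1 in both Calu-KO libraries there were 16 genes. Of these, 13 were protein coding, such as Prkcb, Pnma5, Slc22a18, Hapln4 and Rac2 (limits and examples chosen after their values were seen). In the opposite direction there were 2, the mitochondrial tRNA gene mt-Ti and the small nucleolar RNA gene Gm23706, with 4 to 8 reads per Calu-KO library. The other splits into 2 and 2 gave 0 to 5. They mix the groups, so a gene that differs by group cannot meet the rule there, and they give no background rate. With 1 library on each side, a looser rule, there were 36 and 24 between the WT libraries and 57 and 37 between the Calu-KO libraries. The X chromosome, singled out after the genes were seen, held 5 of the 16 and 3.08% of tested genes, and 2 of these 5, Pnma5 and Xlr3a, lie close together. Too few reads cannot account for the set, since at the WT level the median gene would have had 116 reads in the shallower Calu-KO library, although 2 of the 16 are microRNA genes with 2 to 7 reads in WT. Loss of whole regions would lower neighbours too, and 12.5% of the 16 had a nearest tested neighbour lower by 1 or more on the log2 scale. These were 2 genes, Pnma5 and Xlr3a, which are neighbours of each other, so a local loss there stays open. A loss confined to 1 gene would not lower its neighbours, so this share cannot exclude it. Stable silencing in a clonal population may be one source and the loss of calumenin another; with 1 genotype contrast these were not tested.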
